A study of Mus musculus with 12 samples.

How the data were processed

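RNA of cultured aortic endothelial cells from mice aged 4 weeks was measured on Affymetrix mouse genome expression arrays. The labels give 3 arrays in each of 4 groups and call them biological replicates. The p-values measure the spread between these replicates, and the titles do not say whether each came from its own animal. The titles and genotypes give wild type, Ets1 null, Ets2 null and Ets1/2 null; the free-text descriptions of the single nulls name the gene as wild type, and the titles and genotypes were followed. The deposited values are on a log2 scale with 1 value per probe set, and RMA is named in the processing notes of the submitters. The RMA version, any filter on probe sets, and whether all arrays were normalised together are not given in the sources used here. Arrays give no counts, so their number limits the precision.

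The table held 12 columns and 20523 probe sets. The third column labelled Ets1/2 null equalled the mean of the other two columns of that group in 20521 probe sets (99.9903%, within 1e-06). The largest deviation was 0.585. That column holds no measurement of its own and was left out of the fits, so the arrays labelled double null had n = 2, the other groups n = 3, and the fit had 7 residual degrees of freedom. The plan had named all 12 arrays.

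Gene symbols came from the probe table, and Entrez identifiers of 18788 probe sets matched the RefSeq gene table (GRCm38.p6, used for names and neighbourhood only). Of the probe sets, 18824 carried 1 symbol, 549 several and 1150 none. Each of the 11015 genes was represented by its probe set with the highest mean over the arrays, and 4785 genes had several. Probe sets with several symbols or none entered only a separate count.

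limma 3.58.1 in R 4.3.3 fitted a mean per group across all 11015 genes (lmFit and eBayes, two-sided). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 differences are limma's standard errors (SE) unless stated otherwise. The 6 comparisons were each null against wild type, the double null against each single null, and the Ets1 by Ets2 interaction, which is the effect of Ets2 loss in Ets1 null cells minus its effect in cells with Ets1. An F test took all groups at once. pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

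The arrays labelled double null had lower values over most genes, so each comparison with them is also given after each array was centred on its median over all genes. Changes there are reported where they were called in the deposited and in the centred values. "Centred" values in the text are the latter.

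The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named up to 12 rises and 12 falls per comparison with wild type, 6 and 6 for the double null against a single null, and 5 and 5 for the interaction. A gene had to be called, to lie above the median of all genes in its brighter group and, except in the interaction, to have every array of a group above every array of the other. Ets1 and Ets2 were always named, with up to 4 members per list. Genes named outside the rule were chosen after their values were seen and are marked so.

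There were 22 lists: endothelial, arterial and Notch, venous and lymphatic, smooth muscle and pericyte, fibroblast, leukocyte, epithelial and mesothelial, matrix proteases, angiogenic ligands and receptors, survival factors, apoptosis effectors, cell cycle, p53 targets, interferon, inflammation and adhesion, ERK immediate-early, ETS family, basement membrane, TGF-beta and BMP, hypoxia and glycolysis, cholesterol synthesis, and the endoplasmic reticulum stress and ATF4 response. camera compared each list with all other genes at a preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Member counts are given over all genes and adjusted over the list alone. Markers of other cell types were covered in part: 12 of 42 endothelial, 25 of 30 fibroblast, 15 of 21 smooth muscle, 7 of 28 leukocyte and 7 of 18 epithelial genes were on the table. Sex was read from Xist and the Y-linked Eif2s3y, a log2 value above 6 counting as male.

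Tested on simulated data of 11015 genes with 50 changed per size, Ets1 null against wild type recovered 50% of changes of 1 (log2), 86% of 2 and 92% of 3, with 5 false calls. Ets2 null against wild type recovered 44%, 82% and 94% with 6 false calls. The double null against wild type, with 2 arrays, recovered 28%, 86% and 96% with 8 false calls. Of changes of 0.5, these comparisons recovered 2%, 4% and 0%. The simulated noise was independent around 1 mean per gene, with no array offset, outlying array or disagreement between probe sets. These rates therefore need not hold for the real arrays.

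The alternatives fixed in advance left out each array in turn, took the replicate number as a block, used only the arrays of the compared groups, averaged probe sets, left out the dimmest 3672 genes, moderated variances with trend and robust, weighted arrays, applied quantile or cyclic loess normalization, tested lists with an estimated correlation or fry, restricted the concordance to brighter genes, and used windows of 10 and 40 Mb in place of 20 Mb around the targeted genes. Added after seeing the data were all 12 columns, centring, a term for male arrays, an estimated correlation on centred arrays for cell cycle genes, leaving out wild-type array 3 and Ets2 null array 3 together, and counting only genes of which the 2 brightest probe sets (mean above 8) were called in the same direction. Overlaps of calls were set beside 100 simulations of unchanged groups sharing the controls. Raw intensities were not analysed here.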

Results

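Ets1 and Ets2 are related transcription factors of endothelial cells. Their loss, alone and together, was compared in cultured aortic endothelial cells with 3 wild-type, 3 Ets1 null and 3 Ets2 null arrays and 2 arrays labelled double null. Wild-type and Ets1 null cells had received a lentivirus with egfp, and Ets2 null cells and those labelled double null a virus with egfp-Cre, the recombinase that deletes the floxed Ets2 alleles. Cre and Ets2 loss therefore went together, and Ets1 null cells also carried floxed Ets2 alleles that wild-type cells lacked.

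The median log2 value lay between 9.05 and 9.15 in the 9 arrays of the other groups and at 8.29 and 8.3 in the arrays labelled double null. In the latter 2 arrays, 1945 probe sets (9.477%) never exceeded 6.5, against 202 (0.984%) in the 3 wild-type, 381 (1.856%) in the 3 Ets1 null and 279 (1.359%) in the 3 Ets2 null arrays. Over the 9 other arrays together only 3 (0.015%) never did, so the probe sets may have been kept for brightness in those arrays. A maximum over 2 arrays also passes a limit less often than one over 3. Pearson's r between arrays of a group was 0.951, 0.901 and 0.903 in wild type, 0.949 to 0.98 in Ets1 null, 0.897 to 0.974 in Ets2 null and 0.916 in double null. Wild-type array 3 and Ets2 null array 3 had the lowest weights in limma, 0.3 each. Xist and Eif2s3y marked wild-type array 1 and all 3 Ets2 null arrays as male and the other 7 arrays as female. The 2 brightest probe sets of 3259 genes moved together across genes with r = 0.835 in Ets1 null and 0.806 in Ets2 null against wild type, but with 0.41 in double null against wild type (genes are not independent replicates).

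**Figure D1:**
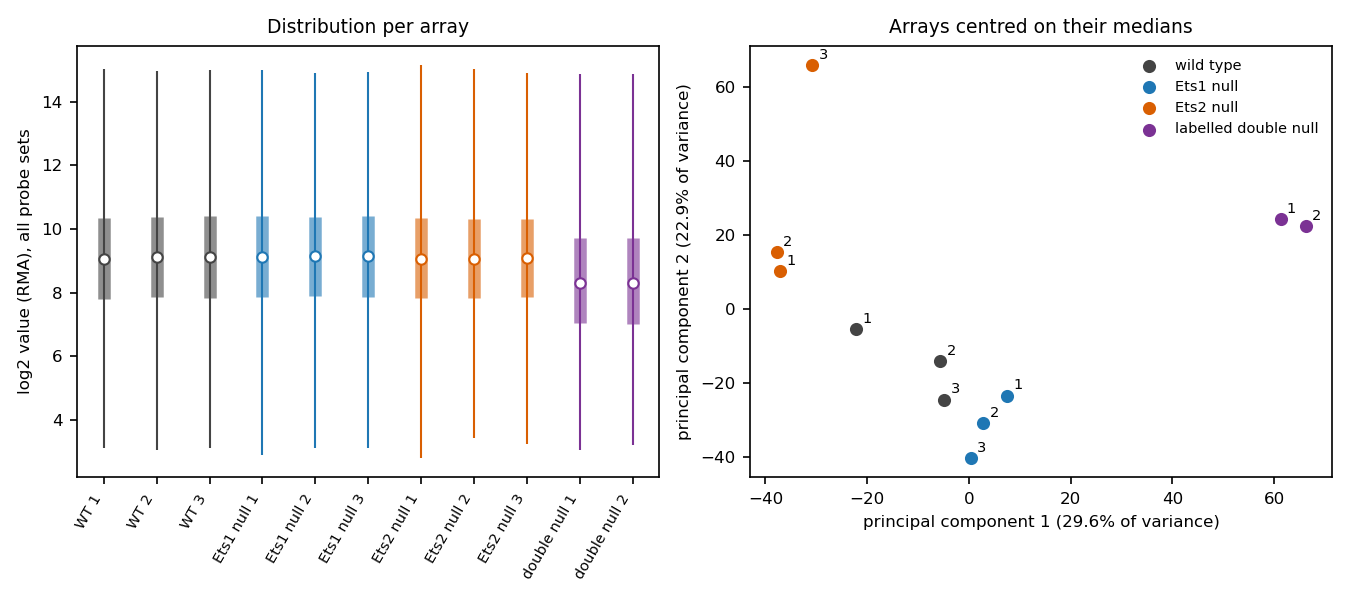
Left, log2 values of all probe sets in each of the 11 arrays (open point, median; thick bar, quartiles; thin line, lowest to highest), with medians at 8.29 and 8.3 in the arrays labelled double null and from 9.05 to 9.15 in the others. Right, principal components 1 (29.6% of the variance) and 2 (22.9%) of the centred arrays, a point per array: the double null arrays lie at 61.3 and 66.2 on the first, and Ets2 null array 3 at 65.8 on the second.

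The brightest of 4 Ets1 probe sets read 10.26, 9.84 and 10.06 in wild type, 8.31, 8.76 and 9.17 in Ets1 null, 9.50, 9.55 and 9.88 in Ets2 null, and 10.02 and 10.29 in the arrays labelled double null. In Ets1 null it lay below every wild-type array, without passing the threshold (-1.31 ± 0.23, SE, n = 3 and 3, adjusted p = 0.203). In double null it was above Ets1 null by 1.41 ± 0.25 (n = 2 and 3, adjusted p = 0.00192; centred 2.16 ± 0.25) and against wild type it had 0.10 ± 0.25 (adjusted p = 0.763) as deposited and 0.81 ± 0.25 (adjusted p = 0.0406) centred. The mean of the Ets1 probe sets gave 0.30 against Ets1 null (adjusted p = 0.319). A dimmer Ets1 probe set went the other way in these arrays, at 6.49 and 7.05 (-2.0 ± 0.27 against wild type, adjusted p = 0.000281; adjusted p = 0.00776 centred). Ets2 (brighter of 2 probe sets) read 9.72, 10.01 and 10.70 in wild type, 10.28, 10.37 and 10.54 in Ets1 null, 9.63, 9.35 and 10.13 in Ets2 null (-0.44 ± 0.38, adjusted p = 0.557), and 11.02 and 9.63 in double null (0.18 ± 0.42, adjusted p = 0.748). The position of these probe sets relative to the deleted exons was not known, so for Ets2 a level near wild type checks nothing about deletion. For Ets1, the Ets1 null arrays give a reference with the same Ets1-/- label. The arrays labelled double null read above that reference in the brightest probe set, but the mean of the probe sets was not called. Those readings do not tell a difference in genotype from one in measurement.

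**Figure D2:**
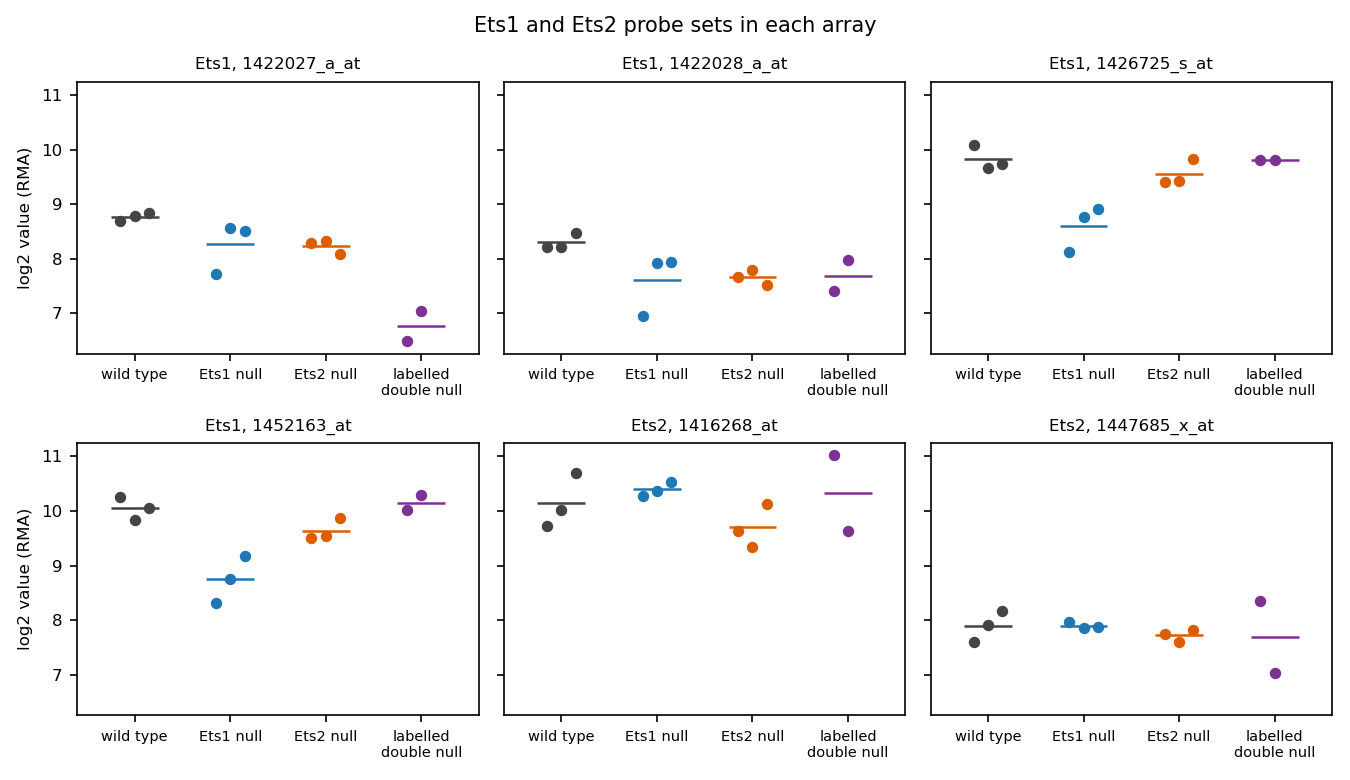
Log2 value (RMA) of the 4 Ets1 and 2 Ets2 probe sets by group; points are arrays and lines are group means. The brightest Ets1 probe set lay between 8.31 and 9.17 in Ets1 null and between 9.50 and 10.29 in the arrays of the other groups.

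Loss of Ets1 alone was read from Ets1 null against wild type. Rnf130, which encodes a membrane-bound E3 ubiquitin ligase, fell by 3.58 ± 0.25 on the log2 scale (n = 3 and 3, adjusted p = 0.00185). It read 10.95, 10.23 and 10.55 in wild type, 6.82, 6.85 and 7.34 in Ets1 null, 11.01, 11.02 and 11.66 in Ets2 null, and 8.15 and 7.87 in the arrays labelled double null, the other group with Ets1-/- in its genotype. Its call held in 22 of 23 alternatives; with only the arrays of these groups the adjusted p was 0.0582. A second, dimmer probe set of Rnf130 did not move (-0.09 ± 0.14), and the mean of probe sets fell by 1.84. Rnf130 was the only gene called by limma among 11015, with 954 at an unadjusted p under 0.05. The count was 9 without wild-type array 2, 15 without wild-type array 3, 12 without Ets1 null array 1, 2 without Ets1 null array 3, and 6 without either double null array.

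Inflammation and adhesion genes were lower in Ets1 null as a list, with 27 of 29 members below wild type and a median of -0.95 (adjusted p = 2.68e-09; adjusted p = 0.528 with an estimated correlation). No member passed over all genes and 3 were lower when adjusted over the list alone. Nfkbiz, a nuclear regulator of NF-kappaB targets, had -1.83 ± 0.34 (adjusted p = 0.229), the related Bcl3 -1.44 ± 0.27 (adjusted p = 0.236), and the chemokine genes Ccl5 and Ccl2 -1.53 ± 0.39 (adjusted p = 0.361) and -4.26 ± 1.38 (adjusted p = 0.501). The list medians by array were 0.71, 0.42 and -1.01 in wild type and -1.04, -1.20 and -0.93 in Ets1 null, so wild-type array 3 lay with the nulls. Without it the adjusted p was 1.46e-18.

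Endothelial markers had a median of -0.49 in Ets1 null, with 10 of 12 members below wild type (adjusted p = 0.011; adjusted p = 0.256 with an estimated correlation). Cd34 (-3.25 ± 1.12, adjusted p = 0.519), the fatty-acid carrier Fabp4 (-3.40 ± 1.31, adjusted p = 0.535) and the TGF-beta co-receptor Eng (-1.22 ± 0.50, adjusted p = 0.545) did not pass over all genes or adjusted over the list alone. Without wild-type array 1, the male one, the endothelial adjusted p was 0.0842, and a term for male arrays gave the same. Interferon genes (28 of 35 lower, median -0.24, adjusted p = 0.011; adjusted p = 0.959 with an estimated correlation) lost their call without wild-type array 1 (0.178), wild-type array 2 (0.618) or Ets1 null array 1 (0.0889). Fibroblast genes (25, median -0.36, adjusted p = 0.0136; adjusted p = 0.798 with an estimated correlation), such as Dpt (-1.70 ± 0.60, adjusted p = 0.519) and Fbln1 (-2.61 ± 1.07, adjusted p = 0.545), lost theirs without wild-type array 2 (0.132). ERK immediate-early genes (31, median -0.23, adjusted p = 0.0312; adjusted p = 0.917 with an estimated correlation) lost theirs without wild-type array 1 (0.171), wild-type array 2 (0.349) or Ets1 null array 3 (0.157), and when centred (0.088). In none of these 3 lists was a member called over all genes or adjusted over the list alone. The remaining 17 lists had adjusted p from 0.182 (matrix proteases) to 0.915 (cell cycle and ETS family); adjusted over the list alone, the arterial gene Notch1 (-0.95 ± 0.18, adjusted p = 0.236 over all genes) and the semaphorin gene Sema3e of the angiogenic list (-3.31 ± 0.46, adjusted p = 0.0887) were lower and Id2 of the TGF-beta list (adjusted p = 0.282) was higher.

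Ets2 null against wild type asked what Ets2 loss does where Ets1 is intact. Genes of oxygen sensing and glycolysis fell: the HIF prolyl hydroxylase gene Egln3 (-2.70 ± 0.41, n = 3 and 3, adjusted p = 0.0416, both probe sets called), the pyruvate dehydrogenase kinase gene Pdk1 (-2.02 ± 0.31, adjusted p = 0.0459) and the collagen prolyl hydroxylase gene P4ha2 (-1.75 ± 0.23, adjusted p = 0.0272). Nfkbiz fell by 2.86 ± 0.34 (adjusted p = 0.0272, both probe sets called), and the immediate-early nuclear receptor gene Nr4a1 fell by 1.69 ± 0.23 (adjusted p = 0.0276). Apoe, the gene of a lipid carrier, rose by 4.80 ± 0.72, and Itih5, which encodes a hyaluronan-binding matrix protein, by 3.98 ± 0.59 (adjusted p = 0.0401 each). The ubiquitin ligase gene Lnx1 rose by 1.67 ± 0.15 (adjusted p = 0.0115) and Ppl, encoding the desmosomal protein periplakin, fell by 1.98 ± 0.20 (adjusted p = 0.0125); these calls held in 19 of 22 and 20 of 23 alternatives.

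Of 11015 genes, 34 were called in Ets2 null, 17 higher and 17 lower, with 2088 at an unadjusted p under 0.05, and 33 of the 34 were also called in centred values (Klhl26 was not, adjusted p = 0.0565). Other rises were the cysteine dioxygenase gene Cdo1 (2.40 ± 0.35), Pcbd1 (2.25 ± 0.36), the acyl-CoA thioesterase gene Acot11 (2.20 ± 0.33), Vkorc1 (0.93 ± 0.15), Klhl26 (0.85 ± 0.13) and Ppcdc (0.74 ± 0.11), with adjusted p from 0.0401 to 0.0481. Other falls were Maff (-1.88 ± 0.22), Ints6 (-1.84 ± 0.29), Avpi1 (-1.48 ± 0.19), Ifrd1 (-1.47 ± 0.20), the kinase gene Mapk6 (-1.41 ± 0.18) and Dcbld2 (-1.29 ± 0.17), with adjusted p from 0.0272 to 0.0479. With the mean of probe sets Ints6 had -0.43 (adjusted p = 0.157), and with a term for male arrays Apoe had 3.02 (adjusted p = 0.265). Each of the 21 genes named by the rule lost its call without some array, with adjusted p up to 0.128: without Ets2 null array 1, no gene was called. The count was 9 without wild-type array 2, 69 without wild-type array 3, 5 and 4 without Ets1 null arrays 2 and 3, 8 and 7 without Ets2 null arrays 2 and 3, and 17 without either double null array. With a term for male arrays (all 3 Ets2 null arrays and 1 wild-type array) 4 genes were called, 0 of them among the 34. These 34 kept their direction and a median of 97.2% of their log2 difference, while the median SE went from 0.2 to 0.29. Wild-type array 1 was the only male control, so that term in effect set Ets2 null against this array alone. The 34 genes were chosen from the same arrays, so their kept direction does not tell sex from Ets2 loss.

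**Figure D3:**
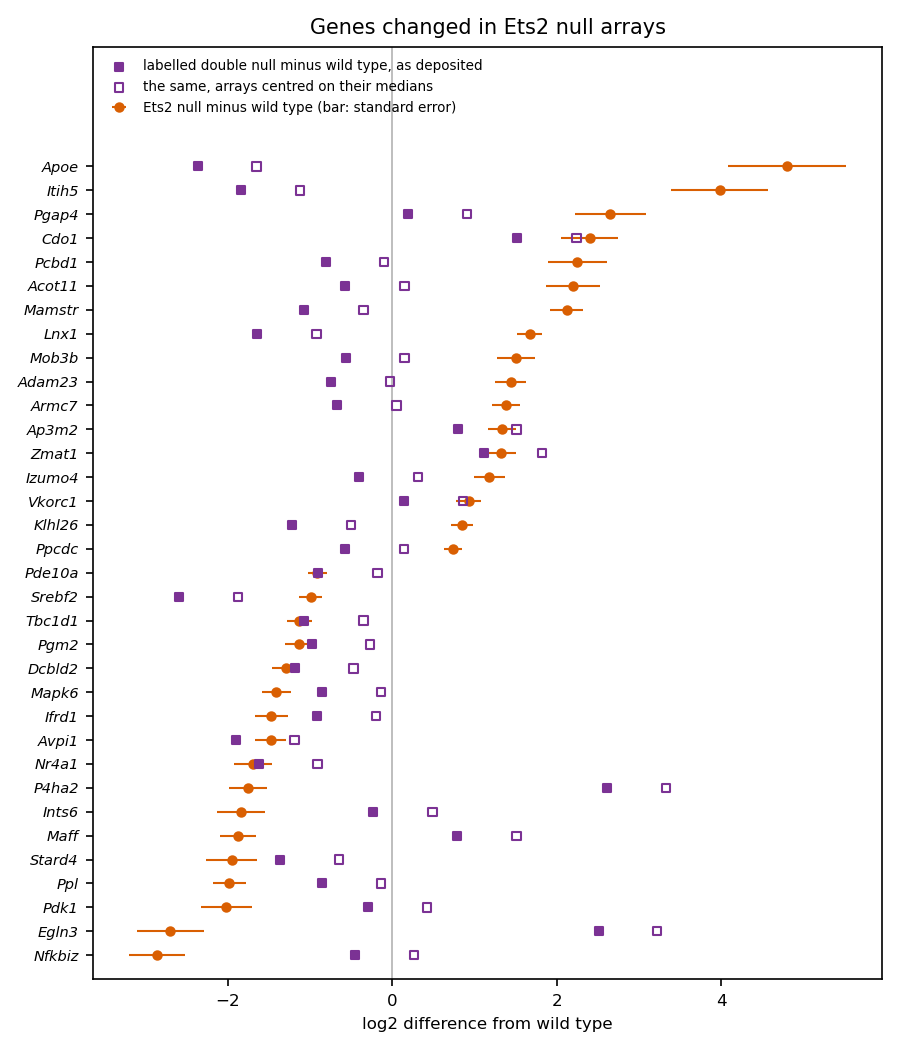
Log2 difference from wild type of the 34 genes called in Ets2 null; circles are Ets2 null with SE bars, filled squares the arrays labelled double null as deposited and open squares the same arrays centred. Egln3 and P4ha2 lay at -2.70 and -1.75 in Ets2 null and at 2.51 and 2.61 in the arrays labelled double null.

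Hypoxia and glycolysis genes were lower in Ets2 null as a list, with 29 of 31 members below wild type and a median of -0.83 (adjusted p = 2.26e-11; adjusted p = 0.584 with an estimated correlation). Over all genes P4ha2, Egln3 and Pdk1 were called, and 16 were lower adjusted over the list alone, among them the hexokinase gene Hk2 (-2.61 ± 0.43, adjusted p = 0.0532 over all genes). The list medians of the 3 Ets2 null arrays were -0.79, -0.79 and -0.66, and with a term for male arrays the adjusted p was 5.04e-08. Cholesterol synthesis genes were lower in 20 of 20 members, with a median of -1.07 (adjusted p = 4.52e-10; adjusted p = 0.584 with an estimated correlation). Srebf2, the transcriptional activator of the pathway, fell by 0.99 ± 0.14 (adjusted p = 0.0401) and the sterol carrier gene Stard4 fell by 1.95 ± 0.31 (adjusted p = 0.0481). Srebf2 lost its call without each array except wild-type arrays 1 and 3 (0.0552 to 0.12), and Stard4 without each except wild-type array 1 (0.0534 to 0.128). Adjusted over the list alone, 11 were lower, and Sqle (-1.75 ± 0.33, adjusted p = 0.0638) and Msmo1 (-1.91 ± 0.39, adjusted p = 0.0725) missed the threshold over all genes. The cholesterol medians by array were -0.44, 0.44 and 0.03 in wild type and -1.16, -1.18 and -0.83 in Ets2 null. Wild-type array 1, the male one, thus lay below the female ones, and sex stays open for this list. With a term for male arrays the cholesterol adjusted p was 2.82e-06. For this list and the hypoxia list, that term rests on a single male control.

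Inflammation and adhesion genes were lower in 25 of 29 members in Ets2 null, with a median of -0.92 (adjusted p = 6.12e-06; adjusted p = 0.584 with an estimated correlation). The list medians by array were 0.71, 0.42 and -1.01 in wild type and -1.14, -0.87 and -0.80 in Ets2 null, so here too wild-type array 3 lay with the nulls. Without it the adjusted p was 1.76e-13. Nfkbiz was called over all genes and 6 were lower adjusted over the list alone; the prostaglandin synthase gene Ptgs2 had -3.93 ± 0.74 (adjusted p = 0.0631) and Ccl5 -1.66 ± 0.39 (adjusted p = 0.0962). ERK immediate-early genes had a median of -0.64 (31 genes, adjusted p = 0.000158; adjusted p = 0.584 with an estimated correlation), with Nr4a1 called, and 6 lower adjusted over the list alone; Ier3 (-3.14 ± 0.68, adjusted p = 0.079) and Dusp1 (-2.79 ± 0.67, adjusted p = 0.0987) missed the threshold. Without Ets2 null array 3 the ERK adjusted p was 0.204.

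Cell cycle genes had a median of -1.36 in Ets2 null, with 50 of 51 below wild type (adjusted p = 1.82e-07; adjusted p = 0.584 with an estimated correlation). The medians by array were 0.06, -0.20 and -4.18, so Ets2 null array 3 alone was low, and without it the adjusted p was 0.229. The proliferation marker Mki67, chosen after its values were seen, read 10.41 (SD 3.29, n = 3) against 12.31 (SD 0.03, n = 3) in wild type, and no member passed over all genes or adjusted over the list alone. p53 targets had a median of 0.46, with 26 of 32 higher (adjusted p = 0.00663; adjusted p = 0.584 with an estimated correlation), and lost their call without wild-type array 3 (0.454) or with a term for male arrays (0.291). Interferon genes had a median of -0.32, with 29 of 35 lower (adjusted p = 0.00813; adjusted p = 0.584 with an estimated correlation), and lost theirs without wild-type array 1 (0.198), wild-type array 2 (0.287) or Ets2 null array 1 (0.1). Neither list had a member called over all genes or adjusted over the list alone. Of the other 15 lists, the lowest adjusted p was 0.345 (fibroblast, venous), with endothelial at 0.4, epithelial 0.411, leukocyte 0.432 and smooth muscle 0.789. The pericyte gene Rgs5 (4.94 ± 1.43, adjusted p = 0.131), the smooth muscle actin gene Acta2 (-2.67 ± 0.91, adjusted p = 0.177) and Col1a1 (-2.17 ± 0.54, adjusted p = 0.103) did not pass.

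**Figure D4:**
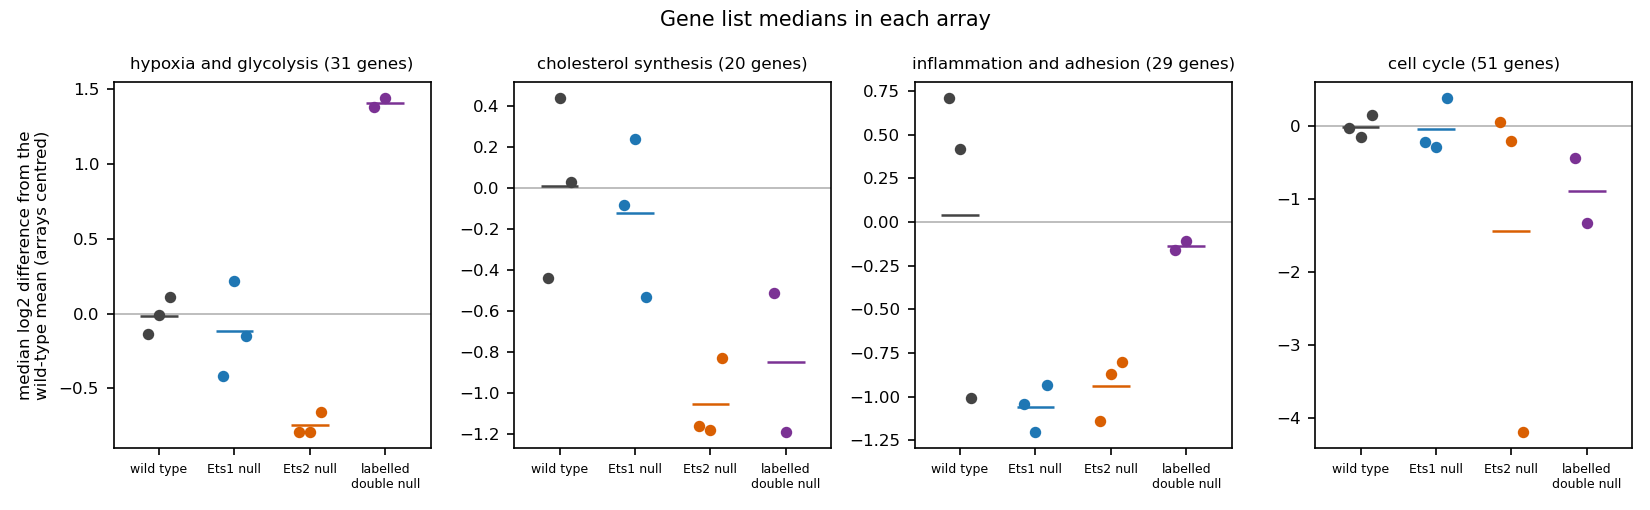
Median log2 difference from the wild-type mean of 4 gene lists in each centred array (hypoxia and glycolysis, 31 genes; cholesterol synthesis, 20; inflammation and adhesion, 29; cell cycle, 51); points are arrays and lines group means. The hypoxia medians were -0.79, -0.79 and -0.66 in Ets2 null and 1.38 and 1.44 in the arrays labelled double null.

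Loss of both factors was read from double null against wild type, where Cre also differs. Genes of oxygen sensing and glycolysis were higher: P4ha2 rose by 2.61 ± 0.26 (n = 2 and 3, adjusted p = 9.12e-05; centred 3.33) and the glycolytic enzyme gene Aldoc by 3.08 ± 0.49 (adjusted p = 0.000977; centred 3.80). The HIF prolyl hydroxylase genes Egln1 and Egln3 rose by 2.05 ± 0.30 (adjusted p = 0.000624; centred 2.76) and 2.51 ± 0.46 (adjusted p = 0.00206; centred 3.22), each with both probe sets called. Bcl2l1, which encodes the survival factor Bcl-xL, fell by 4.03 ± 0.42 (adjusted p = 0.00012, centred -3.31), from 10.25, 9.48 and 8.60 to 5.25 and 5.58. It had only 1 probe set, so its fall has no second reading in this or the later comparisons. Both double null values lay under 6.5, where background limits how well a fall is measured. Srebf2 fell by 2.59 ± 0.16 (adjusted p = 1.28e-05; centred -1.88, both probe sets called). Ampd3, an AMP deaminase gene, rose by 2.55 ± 0.19 (adjusted p = 2.64e-05).

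In double null against wild type 5022 of 11015 genes were called, 258 higher and 4764 lower, with 5902 at an unadjusted p under 0.05. The median difference over all genes was -0.61, and after centring 3091 were called, 1779 higher and 1312 lower. In both, 258 were higher and 1312 lower, while 8 changed direction. The share of called genes that were higher went from 5.1% to 57.6% with centring, and was 48.4% with quantile normalization or loess. The count in a direction thus depended on where 0 was placed. Without double null array 2 the 258 higher genes were 152. For Actb, a probe set fell by 1.43 ± 0.24 and another rose by 1.16 ± 0.38, an example chosen after its values were seen. Of 3259 genes with 2 bright probe sets, after centring 284 were higher and 160 lower in both and 116 were called in opposite directions (130 and 90 against Ets1 null and Ets2 null).

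Further rises in the arrays labelled double null were the hypoxia-induced Ankrd37 (3.09 ± 0.67, adjusted p = 0.00512), the matrix proteoglycan gene Prelp (2.93 ± 0.61, adjusted p = 0.00406) and the transglutaminase gene Tgm2 (2.51 ± 0.50, adjusted p = 0.00319), the last 2 in both probe sets. With the mean of probe sets Prelp had 1.89, Tgm2 1.13 and Ppp1r3c 1.30 (adjusted p = 0.205 for the last). Further falls were the anaphase-promoting complex gene Anapc5 (-4.89 ± 0.25), Tmem120a (-4.22 ± 0.23), the centromere gene Cenpb (-4.24 ± 0.31), the sialyltransferase gene St3gal4 (-3.89 ± 0.27) and the nucleoside transporter gene Slc29a1 (-4.10 ± 0.44), with adjusted p from 9.28e-06 to 0.000125. Of the 24 genes named by the rule, 14 kept their call without each array in turn. Without double null array 2, calls were lost for Ppp1r3c (3.82 ± 0.99; 0.0792), Inhba (2.41 ± 0.66; 0.136), Grb10 (-4.54 ± 1.10; 0.0825), Mbnl3 (-4.26 ± 1.03; 0.083), Thbd (-4.02 ± 1.08; 0.0986, with -1.91), Ube2c (-4.19 ± 1.30; 0.169) and Vldlr (2.8 ± 0.93; 0.14). Without double null array 1 they were lost for Mef2c (2.93 ± 0.69; 0.0589), Mtss1 (2.48 ± 0.63; 0.0525), Nptx1 (-5.65 ± 1.44; 0.0689) and Vldlr (0.0903), and Thbd went to -6.13. Vldlr also lost its call without wild-type array 2 (1.78, 0.0527), wild-type array 3 (0.0605) or Ets1 null arrays 2 and 3 (0.0511 and 0.0507), and Ube2c without wild-type arrays 1 and 3 (0.0522 and 0.0647). Ube2c was not called when centred (adjusted p = 0.0765).

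Hypoxia and glycolysis genes were higher in double null as a list, with a median of 0.72 (centred 1.43), 24 of 31 positive, adjusted p = 2.8e-14 (centred 1.31e-07; adjusted p = 0.465 with an estimated correlation). Over all genes 10 were higher in the deposited and the centred values and 1 lower as deposited, and adjusted over the list alone again 10 and 1. Of the 15 members with a second probe set, 7 were higher in both and 4 were called in opposite directions. Pfkp rose by 2.09 ± 0.27 (adjusted p = 0.000317), but the mean of its probe sets gave -0.65. Cholesterol synthesis genes were lower, with a median of -1.63 (centred -0.91), 14 lower over all genes, 7 of them also centred, and 16 adjusted over the list alone (adjusted p = 0.0371, centred 0.000357; adjusted p = 0.766 with an estimated correlation). Dhcr7, encoding the last enzyme of the pathway, fell by 2.44 ± 0.39 (adjusted p = 0.00104; centred -1.73). Pmvk (-1.74 ± 0.28, adjusted p = 0.00101; centred -1.03) and Hsd17b7 (-1.64 ± 0.23; centred -0.92) fell as well. The cholesterol call was lost without wild-type array 2 (0.0646), wild-type array 3 (0.109), Ets2 null array 3 (0.0562) or double null array 2 (0.236). It was also lost with the replicate block, the mean of probe sets or array weights, and without the dimmest genes or the 2 arrays that stand apart.

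By camera the smooth muscle, fibroblast, angiogenic and basement membrane lists were called higher than other genes as deposited (adjusted p = 0.0371 each). They were not called when centred (0.753, 0.873, 0.946 and 0.694) or with an estimated correlation (adjusted p from 0.465 to 0.625). camera sets each difference against its SE. Under a shift common to all genes, such a call can come from the spread of the genes rather than from a smaller fall. Among angiogenic genes Plxnd1 (-2.29 ± 0.39), its ligand Sema3e (-3.18 ± 0.51) and the venous receptor gene Ephb4 (-1.37 ± 0.17, adjusted p = 0.000256; centred -0.66) were lower in the deposited and the centred values. The smooth muscle call was lost without wild-type array 1 (0.0657), wild-type array 3 (0.109) or double null array 1 (0.524), and the fibroblast call without wild-type array 3 (0.109), Ets2 null array 1 (0.0544) or double null array 1 (0.498). The angiogenic call was lost without wild-type array 3 (0.109) or double null array 1 (0.213), and the basement membrane call without wild-type array 3 (0.109), double null array 1 (0.059) or double null array 2 (0.0707). Cell cycle genes went from an adjusted p of 0.952 to 0.00248 when centred (median -0.84; centred adjusted p = 0.955 with an estimated correlation), with list medians of -0.44 and -1.33 in the 2 double null arrays. Endothelial markers were not called (0.507), with 7 of 12 lower as deposited and 0 in both; Kdr, the VEGF receptor 2 gene, had -1.02 and -0.30 when centred. The other lists had adjusted p from 0.0619 to 0.952.

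Double null against Ets1 null asked what Ets2 loss, with Cre, does where Ets1 is absent. P4ha2 rose by 2.72 ± 0.26 (n = 2 and 3, adjusted p = 6.94e-05), Aldoc by 3.23 ± 0.49 (adjusted p = 0.000763) and Egln3 by 2.70 ± 0.46 (adjusted p = 0.00139). Tmem45a, a hypoxia-responsive membrane protein gene, rose by 4.01 ± 0.83 (adjusted p = 0.00403), and Vldlr, the very-low-density lipoprotein receptor gene, by 4.10 ± 0.93 (adjusted p = 0.00664). The death-associated kinase gene Dapk3 fell by 4.63 ± 0.18 (adjusted p = 6.03e-06). Anapc5 (-4.98 ± 0.25), Cenpb (-4.88 ± 0.31), the protease gene Ctse (-4.68 ± 0.66), Slc29a1 (-4.51 ± 0.44) and Bcl2l1 (-4.49 ± 0.42) fell as well (adjusted p from 6.58e-06 to 0.000522). Other rises each depended on an array. Lcn2 (5.49 ± 1.72) lost its call without Ets1 null arrays 1 (0.0753) and 2 (0.0859) and double null arrays 1 (0.0652) and 2 (0.142). Ppp1r3c (3.50 ± 0.99) lost its call without Ets1 null array 2 (0.059) and double null array 2 (0.105) and with the mean of probe sets (0.93, 0.363), and the HIF target Car9 (3.31 ± 0.80) without double null array 1 (0.0799). Nptx1 (-4.75 ± 1.44) was not called when centred (0.0687) and was lost without Ets1 null arrays 2 (0.0764) and 3 (0.0533) and double null arrays 1 (0.128) and 2 (0.0575).

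Against Ets1 null, 4868 genes were called, 191 higher and 4677 lower, around a median of -0.58. Without Ets1 null arrays 2 and 3 the higher genes were 110 and 105. Centred, 3143 were called, 1899 higher and 1244 lower, and 191 higher and 1244 lower were common to both. Hypoxia and glycolysis genes were higher (median 0.72, centred 1.47; adjusted p = 4.04e-18, centred 1.85e-08; adjusted p = 0.2 with an estimated correlation), 12 higher and 1 lower over all genes and adjusted over the list alone. Cholesterol synthesis genes were lower (median -1.52, centred -0.76; adjusted p = 0.0359, centred 0.000489; adjusted p = 0.809 with an estimated correlation), 13 over all genes, 6 of them also centred, and 15 adjusted over the list alone. Srebf2 (-2.72 ± 0.16, adjusted p = 8.68e-06), Fdps (-3.48 ± 0.55, adjusted p = 0.001) and Ebp (-2.43 ± 0.28, adjusted p = 0.000182) fell. That list call was lost without wild-type array 3 (0.0643), Ets1 null arrays 1 (0.0534) and 2 (0.0687), Ets2 null array 3 (0.0579) or double null array 2 (0.358). It was also lost with the replicate block or the mean of probe sets, and without the dimmest genes or the 2 arrays that stand apart. Inflammation genes were called as deposited (4.74e-06; adjusted p = 0.451 with an estimated correlation) but not centred (0.227); 4 were higher in both, among them Ptgs2 (3.04 ± 0.82, adjusted p = 0.0154; 0.0711 and 0.0589 without double null arrays 1 and 2) and Ccl5 (1.70 ± 0.44, adjusted p = 0.012; 0.073 without double null array 1). The fibroblast, smooth muscle, angiogenic, matrix protease, basement membrane, ERK and TGF-beta lists were called higher than other genes as deposited. The ETS family was called lower (adjusted p from 0.000209 to 0.0426 over these lists). None of these lists was called when centred (0.0698 to 0.941) or with an estimated correlation (0.194 to 0.639). Without double null array 1 or Ets1 null array 1 the smooth muscle adjusted p was 0.752 and 0.154. The ERK call was lost without Ets1 null array 1 (0.0534), Ets2 null array 3 (0.0855) or double null array 2 (0.214), and the TGF-beta call without Ets1 null arrays 1 and 2 (0.0509 and 0.0543) or double null array 1 (0.119). The ETS family call was lost without wild-type array 3 (0.0658), Ets1 null arrays 1 and 2 (0.0725 and 0.0514) or double null arrays 1 and 2 (0.119 and 0.0635). Cell cycle genes went from an adjusted p of 0.944 to 0.000909 when centred (centred adjusted p = 0.977 with an estimated correlation), with list medians of -0.44 and -1.33 in the 2 double null arrays. The other lists had 0.291 to 0.986 as deposited.

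Double null against Ets2 null asked what Ets1 loss does where Ets2 is absent and both groups received Cre; here the Ets2 null arrays were male and the double null arrays female. Egln3 rose by 5.21 ± 0.46 (n = 2 and 3, adjusted p = 4.62e-05, both probe sets called), P4ha2 by 4.37 ± 0.26 (adjusted p = 8.58e-06) and Hk2 by 4.80 ± 0.48 (adjusted p = 8.75e-05). Ptgs2 rose by 6.09 ± 0.82 (adjusted p = 0.000409), while falls were seen for Apoe (-7.17 ± 0.80, adjusted p = 0.000151; -4.49, adjusted p = 0.00944 with a term for male arrays), Itih5 (-5.82 ± 0.66, adjusted p = 0.000165) and the platelet-activating factor hydrolase gene Pla2g7 (-5.42 ± 0.85, adjusted p = 0.000901). Rnf130 fell by 3.22 ± 0.28 (adjusted p = 4.75e-05; centred -2.53 ± 0.28). Notch1 fell by 2.99 ± 0.20 (adjusted p = 1.54e-05), and Bcl2l1 fell by 4.35 ± 0.42 (adjusted p = 7.99e-05).

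Against Ets2 null, 5075 genes were called, 333 higher and 4742 lower, around a median of -0.57. Centred, 3315 were called, 1861 higher and 1454 lower, with 333 higher and 1454 lower common to both. With a term for male arrays 2159 were called, 59 higher and 2100 lower. Xist (5.66 ± 1.31, adjusted p = 0.00705) and Eif2s3y (-5.99 ± 1.53, adjusted p = 0.0111) differed as female against male; Eif2s3y lost its call without double null array 2 (0.0527) and read 0.11 with the male term, where Xist read 0.60. The collagen cross-linking enzyme gene Lox (5.25 ± 1.33, both probe sets called) and Fhl1 (4.98 ± 1.12) rose but lost their calls without double null array 1 (0.0628 and 0.0503), Lox also with the male term (1.41, 0.579), and Vnn1 rose by 5.11 ± 1.10 (adjusted p = 0.00488). Nptx1 fell by 6.40 ± 1.44 (adjusted p = 0.00597). The adipocyte hormone gene Adipoq (-6.32 ± 2.21, adjusted p = 0.0422) was not called when centred (0.082) and lost its call without Ets1 null arrays 1, 2 and 3 (0.0582, 0.0604 and 0.0598), Ets2 null arrays 2 and 3 (0.107 and 0.108) or double null arrays 1 and 2 (0.101 and 0.162).

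Hypoxia and glycolysis genes were higher than in Ets2 null in 28 of 31 members, with a median of 1.67 (centred 2.37; adjusted p = 1.14e-28, centred 1.5e-13; adjusted p = 0.135 with an estimated correlation), 21 higher and 1 lower over all genes and 26 and 1 adjusted over the list alone. Of 15 members with a second probe set, 10 were higher in both and 3 were called in opposite directions. The inflammation, ERK, cell cycle, angiogenic and smooth muscle lists were called as deposited (adjusted p from 7.86e-05 to 0.0214) but not centred (0.36 to 0.978), nor with an estimated correlation (0.162 to 0.738). The smooth muscle call was lost without Ets2 null array 2 (0.0841) or double null array 1 (0.338), the angiogenic call without double null array 1 (0.0644) and the ERK call without Ets2 null array 3 (0.0646). The cell cycle call was lost without double null array 1 (0.0644) and turned to lower without Ets2 null array 3 (0.0314). Endothelial markers (adjusted p = 0.209) held 2 genes lower in both, the fenestral diaphragm gene Plvap (-3.19 ± 0.69, adjusted p = 0.00496) and Eng (-2.97 ± 0.56, adjusted p = 0.0024), neither called with the male term (-1.99, 0.233 and -1.43, 0.195). Fibroblast genes (0.126) moved apart, with Col1a1 at 2.72 ± 0.61 (adjusted p = 0.00589, both probe sets called), Dpt at -4.86 ± 0.67 (adjusted p = 0.000447) and Gsn at -2.44 ± 0.20 (adjusted p = 2.94e-05), and Acta2 was higher by 3.0 ± 1.02 (adjusted p = 0.0373). Acta2 lost its call without wild-type array 1 (0.051), Ets1 null array 2 (0.0508), Ets2 null arrays 1, 2 and 3 (0.0735, 0.0727 and 0.0738) or double null array 1 (1.23, 0.32), and read 4.77 without double null array 2.

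The interaction asked whether Ets2 loss, with Cre, had the same log2 effect in Ets1 null cells as in cells with Ets1. Sex enters this term too. The Ets2 null arrays were male and wild type held 1 male and 2 female arrays, while both groups labelled Ets1-/- were female. The hypoxia and glycolysis list was lower in Ets2 null against wild type and higher in double null against Ets1 null. Its interaction median was 1.69 (centred 2.43; adjusted p = 5.96e-29, centred 1.41e-14; adjusted p = 0.0657 with an estimated correlation), with 21 members higher and 1 lower over all genes and 23 and 1 adjusted over the list alone. Egln3 had an interaction of 5.40 (adjusted p = 0.000405) and P4ha2 of 4.47 (adjusted p = 8.15e-05). Inflammation genes had a median of 0.93 (centred 1.67; adjusted p = 4.79e-11, centred 0.00217; adjusted p = 0.27 with an estimated correlation), with 10 higher and 2 lower over all genes and adjusted over the list alone. Among them were Ptgs2 (6.97 ± 1.11, adjusted p = 0.0019), Nfkbiz (4.24 ± 0.51, adjusted p = 0.000526, both probe sets called, mean of probe sets 2.82) and Ccl5 (3.36 ± 0.59, adjusted p = 0.00304). Apoe (-5.89 ± 1.08, adjusted p = 0.0037), Pla2g7 (-6.02 ± 1.14, adjusted p = 0.00442), Anapc5 (-5.16 ± 0.33, adjusted p = 7.08e-05) and Dapk3 (-5.12 ± 0.24, adjusted p = 4.41e-05) had the opposite sign.

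An interaction was called for 3438 genes, 165 higher and 3273 lower, around a median of -0.57. With a term for male arrays, which rests on a single male control, 2385 were called, 96 higher and 2289 lower. Centred, 1562 were called, 800 higher and 762 lower, with 165 higher and 762 lower common to both. Lcn2 (8.61 ± 2.31, adjusted p = 0.0211) lost its call without Ets1 null array 2 (0.0512) or double null array 2 (0.0704). The chemokine gene Ccl2 (7.46 ± 2.07) lost its call without wild-type array 2 (0.0529), Ets1 null arrays 1 and 2 (0.0525 and 0.0512), Ets2 null array 1 (0.0503) or double null arrays 1 and 2 (0.0598 and 0.0675). Ccl7 (5.66 ± 1.67) lost its call without wild-type array 2 (0.0636), Ets1 null arrays 1 and 2 (0.0634 and 0.0658), Ets2 null arrays 1, 2 and 3 (0.0586, 0.0571 and 0.0502) or double null array 1 (0.116). The cytokine gene Lif (6.28 ± 1.80) did so without wild-type arrays 1 and 2 (0.0519 and 0.0591), Ets1 null arrays 2 and 3 (0.0573 and 0.0556), Ets2 null array 1 (0.0548) or double null array 2 (0.101). Rgs5 (-7.17 ± 2.14, adjusted p = 0.0317) did so without each array except Ets1 null array 1 and Ets2 null array 2 (0.052 to 0.0988), and when centred (0.0754). The ERK, angiogenic, cell cycle, fibroblast, basement membrane, matrix protease and smooth muscle lists were called as deposited (adjusted p from 1.96e-05 to 0.0402) but not centred (0.202 to 0.886), nor with an estimated correlation (0.0657 to 0.782). The fibroblast call was lost without Ets2 null array 1 (0.0577) or double null array 1 (0.16), and the smooth muscle call without wild-type array 2 (0.237), Ets1 null array 1 (0.131), Ets2 null arrays 1 and 2 (0.0577 and 0.105) or double null array 1 (0.381). The basement membrane call was lost without wild-type array 1 (0.0501), Ets1 null array 2 (0.0689) or Ets2 null array 1 (0.0577). The matrix protease call was lost without wild-type arrays 1 and 2 (0.186 and 0.125), Ets1 null array 1 (0.0722), Ets2 null arrays 1 and 2 (0.0626 and 0.0523) or double null array 2 (0.0805). Without Ets2 null array 3 the cell cycle list turned to lower (0.0269).

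Across all 4 groups 5263 genes differed by limma's F test, and 3338 after centring. The Ets1 effect with and without Ets2, from comparisons sharing no array, had r = 0.201 (covariance 0.094) across genes, which are not independent replicates. It was 0.117 without wild-type array 1, the male one, 0.308 without double null array 1 and 0.062 without double null array 2. Both comparisons behind this r set female arrays against a group with male arrays, so sex can enter it. The Ets2 effect with and without Ets1 had r = 0.077 (covariance 0.038), and 0.137 without Ets2 null array 1, -0.04 without Ets2 null array 3, and 0.139 and 0.004 without double null arrays 1 and 2. Of the 34 genes called in Ets2 null, the deposited and centred double null values were both higher for Cdo1, Ap3m2 and Zmat1 (the last 2 chosen after their values were seen) and both lower for Nr4a1, Avpi1 and Srebf2. Egln3, Maff and P4ha2 turned from lower to higher and Lnx1 from higher to lower; the other 24 were not called in both. As deposited, 3 were higher and 11 lower in Ets2 null and double null alike, where 0.398 and 7.35 would arise at random, and 11 went opposite ways. After centring, 49 genes were called in Ets2 null, 26 higher and 23 lower. Of these 49, 8 were higher and 4 lower in centred double null too, where 4.2 and 2.74 would arise at random, and 10 went opposite ways. Ets1 null shared 0 calls with Ets2 null and 1 (Rnf130) with double null. These comparisons share the 3 wild-type arrays, so values across genes agree in part through those controls. Across genes r was 0.12 for Ets1 null with Ets2 null, 0.316 for Ets1 null with double null and 0.147 for Ets2 null with double null, against 0.502, 0.448 and 0.45 for unchanged groups in 100 simulations. The covariances were 0.035, 0.13 and 0.073, against 0.066, 0.065 and 0.066 simulated. The simulations shared 0.01, 0 and 0 calls on average.

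No gene called in either single null lay within 20 Mb of Ets1 or Ets2, where 190 and 71 genes were tested. Of the genes near Ets1, 50 (26.3%) were called in centred double null against wild type, against 28.1% elsewhere (odds ratio 0.92, Fisher's exact test, two-sided, p = 0.626), and near Ets2 15 (21.1%; odds ratio 0.69, Fisher's exact p = 0.233).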

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

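Chosen only after the result was seen were the 3 tests of the lower values in the arrays labelled double null, the test of Ets2 loss or Cre acting alike with and without Ets1, and the alternatives named as added.

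The interaction term, which sets double null minus Ets1 null against Ets2 null minus wild type, was called for 3438 genes (165 higher and 3273 lower; centred 1562, 800 higher and 762 lower). It was also called, at the preset correlation, for hypoxia and glycolysis genes (adjusted p = 5.96e-29; adjusted p = 0.0657 with an estimated correlation) and for inflammation and adhesion genes (adjusted p = 4.79e-11; adjusted p = 0.27 with an estimated correlation). A measurement difference of the double null arrays enters this term, and so does the sex of the arrays. The single genes were Lcn2 (8.61), Ccl2 (7.46), Ptgs2 (6.97), Lif (6.28), Ccl7 (5.66), Rgs5 (-7.17), Pla2g7 (-6.02), Apoe (-5.89), Anapc5 (-5.16) and Dapk3 (-5.12), all log2. In the 1699 probe sets without a single gene symbol, which the comparisons did not use, 0 were called in Ets1 null and 11 in Ets2 null against wild type. Against wild type, Ets1 null and Ets2 null, the arrays labelled double null had 785, 750 and 752 such calls, and the interaction 523.

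The arrays labelled double null read lower over most genes, with a median of -0.61 against wild type. A filter that kept probe sets bright in the other 9 arrays was argued against as the whole cause. Among 1792 probe sets with a double null mean above 11 the median difference was still -0.29, against -0.63 over all named probe sets. The SE of that median, 0.021, came from the spread over probe sets taken as independent, not from the spread between arrays. The 2 brightest probe sets of a gene had r = 0.41 in double null against wild type and at most 0.52 in the 3 double null comparisons, against 0.835 and 0.806 in the single nulls and 0.792 for double null array 1 minus array 2. Such an r does not change with a shift common to all genes. For that shift it decided nothing. A fall in the transcripts of most genes after loss of both factors and a difference in how these arrays were measured both stay open. Beyond the shift, these values argue against changes read alike by each probe set of a gene. After centring, 116 of 3259 genes had their 2 brightest probe sets called in opposite directions against wild type, and 444 in the same direction. Separate normalization or another processing of these arrays stays open, because joint or separate processing is not given in the sources used here.

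The 2 brightest Ets1 probe sets read near wild type as deposited in the arrays labelled double null (0.10 and -0.02), although their genotype gives Ets1-/-, and the brightest above it when centred (0.81); a dimmer one was lower in both the deposited and the centred values. Disagreement between probe sets of these arrays was not excluded. The 4 Ets1 probe sets spread over 2.1 (log2) in double null against wild type, more than in 74.2% of 466 other genes with 4 probe sets. Those genes had a median range of 1.47 and a 95th percentile of 3.64, which was the bound. In Ets1 null the Ets1 range was 0.81. A range under a bound that 95% of genes pass does not speak for this explanation. That these arrays lack the Ets1 null genotype was met by opposing values and could not be decided. Of 99 genes with the lowest p in Ets1 null, 63.6% moved the same way in double null against Ets2 null (exact 95% interval 53.4 to 73.1; all genes 53.9%), and Rnf130 was lower there (centred -2.53 ± 0.28, adjusted p = 0.000503; 1.13% of genes were as low). The bound fixed in advance against this explanation was thereby met. It asked for 60% or more the same way, and for Rnf130 lower by more than 1 and by more than 2 SE. The question was left undecided for reasons outside that bound. The interval includes shares under 60%, and the brightest Ets1 probe sets themselves were not lower. The interval also treats genes as independent, which they are not. Both comparisons set female arrays against a group with male arrays, so sex can add to a shared direction.

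Hypoxia and glycolysis genes were lower in the 3 Ets2 null arrays and higher in those labelled double null. The single Ets2 null array 3 that stands apart was excluded as the source, since the list median without it was -0.9 against -0.83 with it. Loss of Ets2 or Cre acting alike with and without Ets1 should put the centred list median of double null minus Ets1 null below 0, and it was 1.47. By array the list medians were 1.38 and 1.44 in double null and -0.42, 0.22 and -0.15 in Ets1 null, which argues against an alike effect on its own. A measurement difference of the double null arrays was not excluded, so an alike effect beside such a difference stays open. Sex stays open: male wild-type array 1 differed from the mean of the female wild-type arrays by -0.19 (SD of those 0.09), against -0.73 for Ets2 null, from a single male control. An effect of Ets2 loss that turns around without Ets1, a culture difference such as cell density or oxygen, and a measurement difference of the double null arrays were not told apart by any value here.

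Other splits of the arrays were counted for 3 results. The F test gave 5263 genes for the real groups and at most 222 for the other 99 of 100 splits. Only 1 split, the real one, reached that count. This sets aside a random grouping of the 11 arrays, but not an offset of the 2 arrays labelled double null. Those 2 read lower over most genes, and a split that parts them loses that shift. The count therefore says nothing on the single nulls. The 6 arrays of a single null and wild type allow only 10 splits, too few for a share under 0.05: in Ets1 null the real count was 1, the highest other was 1 and 2 splits gave as many, and in Ets2 null the real count was 34, the highest other was 2 and 1 split gave as many.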

How the results depend on the processing

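Among the alternatives, all 12 columns, centring, the male term, leaving out wild-type array 3 with Ets2 null array 3, the call in both probe sets, and an estimated correlation on centred arrays were chosen after seeing the data. Of the alternative values of named genes, 5075 kept their direction and side of the threshold, 437 lost and 8 gained a call and 4 reversed; for lists these numbers were 1316, 257, 9 and 31. The hypoxia list kept its call in each of the 5 comparisons where it was called, under every alternative except an estimated correlation. Under that one no list call was kept. In Ets2 null fry kept hypoxia (0.0354) and cholesterol synthesis (0.039) and lost the cell cycle, ERK, inflammation, interferon and p53 calls. With fry the endothelial, ERK, fibroblast, inflammation and interferon calls in Ets1 null were lost. So were the inflammation calls of double null against each single null and in the interaction, and the ERK call in the interaction.

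The Ets1 null count (1) ranged from 1 to 15 without each array, and was 0 with only the 2 groups, 196 with array weights, 7 with all 12 columns, and 40 without the 2 arrays. Its only called gene lacked a second probe set bright enough for the call in both. The Ets2 null count (34) ranged from 0 to 69 without each array and was 0 with only the 2 groups, 52 with the mean of probe sets, 16 without the dimmest genes, 1044 with array weights, 285 with all 12 columns, 4 with the male term and 7 in both probe sets, where the brightest of such genes gave 16. Array weights gave the 2 arrays standing apart 0.3 each; all 12 columns count a mean as an array. Double null against wild type (5022) gave 2785 with quantile normalization, 2917 with loess, 3091 centred and 444 in both probe sets (after centring, of 3259 genes with 2 bright probe sets, where the brightest alone gave 1127); against Ets1 null (4868) 2594, 2797, 3143 and 423; against Ets2 null (5075) 2951, 3092, 3315 and 491, with 3358 without the dimmest genes and 2159 with the male term; the interaction (3438) 1278, 1421, 1562 and 210; the F test (5263) 3013, 3141 and 3338. Higher and lower genes were 1347 and 1438 with quantile normalization and 1412 and 1505 with loess against wild type, 1198 and 1396 and 1324 and 1473 against Ets1 null, 1382 and 1569 and 1469 and 1623 against Ets2 null, and 461 and 817 and 547 and 874 in the interaction. Centring instead gave more higher than lower genes in each of these 4. The scalings remove the median shift by construction; leaving out each array kept these totals within 1.5 times, but not the higher genes alone: 258 against wild type became 152 without double null array 2, and 191 against Ets1 null became 110 and 105 without Ets1 null arrays 2 and 3. For the other changes the cause was not tested.

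The concordance of the Ets1 effect (0.201) ranged from 0.062 to 0.308 without each array and was 0.123 in brighter genes; that of the Ets2 effect (0.077) ranged from -0.04 to 0.139 and was 0.005 with array weights and -0.047 without the 2 arrays. Reversed were Eif2s3y against Ets2 null with the male term (0.11) and Pfkp with the mean of probe sets (-0.65, -1.04 and -0.31 against wild type, Ets1 null and Ets2 null). fry tests against 0 and so counts the median shift; it turned to lower the smooth muscle, fibroblast, epithelial, angiogenic and basement membrane lists against wild type (0.613, 0.213, 0.0157, 0.0144 and 0.341). Against Ets1 null it did so for the endothelial, smooth muscle, fibroblast, matrix protease, angiogenic, ERK, basement membrane and TGF-beta lists (0.00588, 0.489, 0.857, 0.3, 0.0623, 0.144, 0.857 and 0.0231). Against Ets2 null these were smooth muscle, angiogenic, cell cycle and ERK (0.73, 0.0817, 0.73 and 0.73), and in the interaction smooth muscle, fibroblast, leukocyte, matrix protease, angiogenic, cell cycle and basement membrane (0.646, 0.535, 0.0127, 0.252, 0.64, 0.718 and 0.64). Centring turned to lower the ERK list against Ets1 null (0.941) and the cell cycle list against Ets2 null (0.978) and in the interaction (0.886). The cell cycle list also turned without Ets2 null array 3 (0.0314 and 0.0269) and without the 2 arrays (0.0563 and 0.0496), while it had 7.76e-07 and 1.91e-06 without Ets2 null array 1 and 0.0644 and 0.03 without double null array 1. Near Ets2, the odds ratio in Ets2 null was 6.72 in the 40 Mb window (2 of 103 genes, Fisher's exact p = 0.0401).

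With the replicate number as a block, Ets1 null had 1 gene and Ets2 null 5. The 15 pairs of arrays sharing a number had residual r from -0.323 to 0.104 (median -0.056), and 0 of 11 arrays correlated best with their own number, so the numbers were not used to pair arrays. In the arrays labelled double null, 1945 probe sets never exceeded 6.5, where signal over background limits how far a fall can be measured.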

Other observations

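The centred values and the call in both probe sets were alternatives chosen after seeing the data; no other test in this part was, and the genes are those the lists and the rule named. Among ETS family genes other than the targeted ones, 4 of 12 were lower in the arrays labelled double null as deposited and centred, while the list as a whole missed the threshold (adjusted p = 0.0619; centred 0.0811; adjusted p = 0.625 with an estimated correlation). Erf, an ETS repressor downstream of ERK, had -2.57 ± 0.17 against wild type (n = 2 and 3, adjusted p = 1.7e-05; centred -1.85), Elk1 -1.43 ± 0.13 (adjusted p = 6.58e-05; centred -0.72) and Etv5 -2.07 ± 0.39 (centred -1.36, both probe sets called, mean of probe sets -3.60). As deposited, 9 were lower over all genes and 10 adjusted over the list alone. Notch1 fell by 2.05 ± 0.20 (adjusted p = 9.61e-05; centred -1.34) and Id1, a BMP target, by 2.19 ± 0.24 (adjusted p = 0.00015; centred -1.48), while Skil, a brake on TGF-beta signalling, rose by 1.55 ± 0.36 (centred 2.27).

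Some pro-apoptotic and pro-survival genes were lower in the same arrays, without a call for either list. Such falls were common: over all genes, 4764 of 11015 were lower as deposited and 1312 of these also centred. The genes named here were picked for a low p within their lists. Bad, encoding a BH3-only protein, had -1.88 ± 0.15 (adjusted p = 3.24e-05; centred -1.17), the mitochondrial protease gene Htra2 -2.63 ± 0.27 (adjusted p = 0.000104; centred -1.92), both in both probe sets, and the pore-forming Bak1 -2.18 ± 0.27 (adjusted p = 0.000256; centred -1.47). Akt1 had -1.76 ± 0.22 (adjusted p = 0.00025; centred -1.05, both probe sets called, mean of probe sets -3.76). Apoptosis effectors had 13 of 26 lower, 5 also centred and 13 adjusted over the list alone (adjusted p = 0.952), and survival factors 8 of 16, 3 and 9 (adjusted p = 0.794). The p53 targets Phlda3 (-3.52 ± 0.57, adjusted p = 0.0011; centred -2.80) and Gtse1 (-3.14 ± 0.47), the chaperone gene Sdf2l1 of the endoplasmic reticulum stress list (-2.35 ± 0.18, adjusted p = 2.64e-05; centred -1.64) and the interferon mediator Stat2 (-2.16 ± 0.33, adjusted p = 0.000775; centred -1.45) were lower too, in lists with adjusted p of 0.153, 0.798 and 0.507.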
